A study of Mus musculus with 12 samples.

How the data were processed

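Poly(A) RNA was measured by bulk RNA-seq in 12 mouse libraries of Eµ-Myc B cell lymphoma cells, 4 from culture, 4 from lymph nodes after spread through lymphatic vessels (day 11) and 4 from lymph nodes after spread through the blood (day 18), and groups were taken from the titles. Lymphoma cells were sorted from the lymph nodes before RNA extraction per the labels, which do not give the sort gate or marker. Libraries were stranded and single-end, per the labels' protocols. Reads were checked with FastQC 0.11.9, trimmed with Trimmomatic 0.39, aligned with HISAT2 2.1.0 and counted with HTSeq 2.0.2, per the submitters' processing notes. The files deposited by the authors hold raw counts per gene and library, without normalization, for 56748 versioned Ensembl gene IDs. The build is GRCm39 per the submitters' processing notes. Symbols, biotypes and transcript lengths came from an older annotation of mouse, so no positions are given. A symbol was found for 91.8% of IDs, which hold at least 98.8% of counts in each library, and 67 symbols were shared by 2 IDs, of which the ID with more counts kept the symbol. The 5 summary lines of reads without a gene, 30.3% to 36.5% of reads per library, were left out of library sizes and tests.

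Total assigned counts were 12738568, 5655422, 9148715 and 8441212 in culture 1 to 4, 14855872, 25302016, 12399951 and 19965917 in lymphatic 1 to 4, and 12444690, 11720833, 10218094 and 5286775 in hematogenous 1 to 4. Molecular identifiers were not used here, so intervals and floors cover counting error only. CPM were computed from the counts with TMM factors.

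Genes were tested with edgeR 4.0.16 in R 4.3.3, by a quasi-likelihood F test in a fit of all 12 libraries on group (9 residual degrees of freedom, common dispersion 0.0457), after filterByExpr left 13535 genes. Adjusted p values are Benjamini-Hochberg over all genes of a comparison, two-sided, at a threshold of 0.05, and SE was taken from the fold change and its F value, which is approximate. The comparisons were lymphatic with culture, hematogenous with culture, and lymphatic with hematogenous. The labels give no statistical model. The comparisons, tests, gene lists, naming rule and alternatives were chosen before the data were examined. Exceptions were an alternative without lymphatic 4 and culture 4, the genes named as exceptions of a list, the immunoglobulin and marker genes given for clone and host, and the tests of explanations.

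Lists numbered 46, 36 of gene programmes and 10 of markers of other cell types, with 1175 names of which 6 were not matched. Lists with fewer than 3 tested genes were not tested, which left 42. They were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Counts of genes within a list are given over all tested genes and adjusted over the list alone. Median, mean and test of a list differed in sign only among lists that were not called, 5 against culture for lymphatic, 6 for hematogenous and 8 between the routes.

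Genes are named by a rule. Per comparison these are genes with adjusted p under 0.05, all 4 libraries of the higher group above all 4 of the lower, mean CPM of 10 or more in the higher group, and a known symbol that is not a predicted, receptor segment, mitochondrial or pseudogene name. The 12 largest changes each way were taken, then up to 4 called genes per list with that CPM, and Myc always. A fold against a group with 0 counts is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts the ratio of counts is given with a 95% counting interval. Genes with near-identical copies, among them Oas1a, Ifit3, Tgtp2, Ly6a, Magohb, H2-K1, H2-D1 and ribosomal proteins, can share or lose reads in counting and are uncertain for that reason.

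Separation of groups was tested by PERMANOVA on log2 CPM (prior count 2). For the 3 groups all 5775 splits were enumerated, where random draws had been planned, and for the routes all 35. Library measures were compared by exact permutation of 4 against 4, 36 tests in all, and 0 had an adjusted p under 0.05. With 70 arrangements the lowest possible permutation p is 0.0286, which became 0.343 after adjustment. These tests could therefore hardly pass and do not show that the libraries are alike. Genes detected between the routes, and the immunoglobulin share of each arm against culture, reached that lowest p. Counts of genes and lists were also obtained for splits of the libraries, 35 per comparison with the real one included. For the arms there were 60, the real one and others drawn at random. Unchanged groups that share the culture libraries were simulated 30 times for the overlap of the arms. Replicate numbers occur in each group, and the labels do not say that they mark an animal, day or batch. Correlations of deviations between libraries of the same number ran from −0.181 to 0.0919, 0 of 12 over 0.1, so numbers were not taken to pair the samples.

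The fit was tested on simulated counts with known changes put in for each comparison. All counts were drawn from each gene's mean over the 12 libraries and its spread pooled over groups, at the real library sizes. They hold no other group difference, no library that stands apart and no unequal spread between groups. At 4-fold 90.9%, 84.8% and 87.9% of changed genes were recovered for lymphatic with culture, hematogenous with culture and lymphatic with hematogenous, at 2-fold 55.2%, 47.8% and 59.7%, and at 1.5-fold 13.4%, 23.9% and 16.4%. False calls made up 2.7%, 3.6% and 5.9%. Besides a raised list only 66 or 67 genes were changed at each fold, which makes the adjusted threshold stricter than where many genes change. The rates therefore need not carry over to the real comparisons. There many called genes changed less than 2-fold, since of 3569 called for lymphatic with culture 646 and 758 changed at least 2-fold. Small changes can still be missed. A raised list was called in each comparison, and 0 of 40 unchanged lists. Genes were drawn independently of each other there, so the list test was not tried on lists whose genes move together.

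Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of CPM 1 in at least 4 libraries, a fit of the 2 groups compared only, the replicate number as a block, mitochondrial (37) and immunoglobulin (395) genes left out, each library left out in turn, culture libraries divided between the arms, the 500 most variable genes and a prior count of 0.5 for separation, and the added alternative. DESeq2 gave no adjusted p for 17 genes per comparison, which were kept as missing. The values of 1 gene are not reported here.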

Results

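Poly(A) RNA of Eµ-Myc lymphoma cells, a mouse B cell lymphoma, was counted in 12 libraries. Cultured cells gave 4 libraries, cells sorted from lymph nodes 11 days after injection and reached through lymphatic vessels gave 4, and cells sorted from lymph nodes 18 days after injection and reached through the blood gave 4. The groups are called culture, lymphatic and hematogenous below. Route and day change together between the lymph node groups and cannot be told apart here. The labels give lymph node as the tissue of the cultured cells too, against their titles, and the titles were followed. The labels do not say whether replicates are separate animals or cultures, so the p-values measure only the spread between these samples. Assigned counts ran from 5286775 to 25302016 per library, with group means ± SD of 8995979 ± 2915327 in culture, 18130939 ± 5726016 in lymphatic and 9917598 ± 3223490 in hematogenous libraries, and 13535 genes were tested. Values are CPM as group mean ± SD over 4 libraries, log2 changes carry ± SE, and adjusted p values come from edgeR.

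Lymphoma cells taken from lymph nodes differed from cultured cells along the main axis of variation, and the routes also separated from each other. PC1 held 45.7% of the variance and placed culture at −67.2 to −61.9, lymphatic at 17.2 to 36.7 and hematogenous at 36.3 to 40.5. PC2 held 23.3% and ran from −41.2 to −25.1 in hematogenous libraries to 15.1 to 16.9 in lymphatic 1, 2 and 3 and 87.9 in lymphatic 4. Group explained R² 0.645 of the distances between all libraries (exact permutation p = 1.73e-04, the smallest possible with 5775 splits). Route explained R² 0.407 among lymph node libraries (exact permutation p = 0.0286, the smallest possible with 35 splits), and 0.526 without lymphatic 4. Spearman correlations were 0.991 to 0.994 within culture, 0.986 to 0.993 within hematogenous and 0.933 to 0.990 within lymphatic libraries. Lymphatic 4 carried 15.8% of its counts in ribosomal protein genes (95% Wilson interval 15.79% to 15.83%), against 7.46% to 9.73% in the other 11 libraries.

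**Figure D1:**
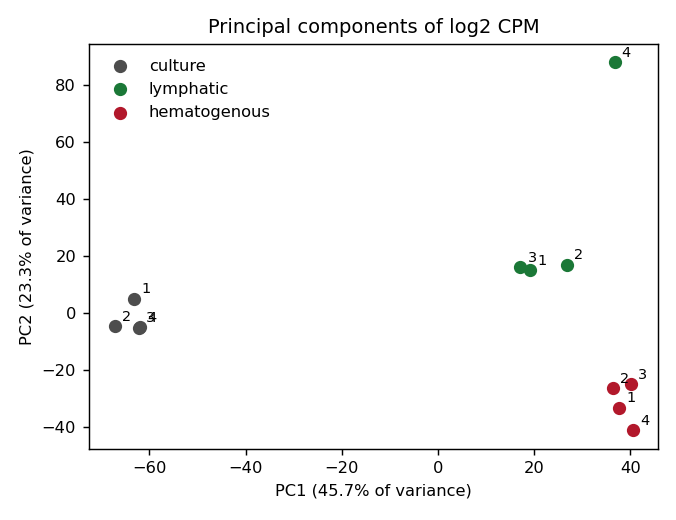
Principal components 1 and 2 of log2 CPM, 1 point per library with the percent of variance on each axis. Culture lies apart on component 1, and lymphatic 4 lies apart from the other lymphatic libraries on component 2.

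Every group carried the same immunoglobulin V segments, so the sorted cells were largely the clone of the culture. Heavy chain V reads came from Ighv3-6, at 347 ± 15.9 CPM in culture, 314 ± 129 in lymphatic and 460 ± 35.7 in hematogenous libraries. Other Ighv genes made up 0.0367%, 3.01% and 0.870% of heavy chain V reads. Igkv3-7 held 98.8%, 97.3% and 97.8% of kappa V reads. Lyz2 of myeloid cells and Trbc2 of T cells were scarce but rose in the lymph node libraries, from 0 counts of either in culture. Lyz2 reached 27.61 ± 14.02 and 11.8 ± 3.20 CPM and Trbc2 8.09 ± 7.27 and 1.18 ± 0.831 CPM in lymphatic and hematogenous libraries. Summed NK cell markers (20.7, 7.78 and 2.17 CPM in culture, lymphatic and hematogenous libraries) and erythroid markers (28.3, 19.2 and 16.4 CPM) did not rise. Klrb1c was nearly all of the NK cell sum in culture but little of it in the lymph node groups (20.2, 0.739 and 0.222 CPM). The other NK cell markers therefore summed higher there on average. The 3 tested erythroid markers ranged from log2 −2.96 to 5.74 in lymphatic and −3.24 to 4.58 in hematogenous libraries. Stromal markers summed to 1.00, 7.10 and 1.54 CPM. Lymphatic 4 held 18.8 CPM of Trbc2, against 2.91 to 5.99 in the other lymphatic libraries. These segments and marker genes were chosen after their values were seen, as were the genes named below as exceptions within a list.

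**Figure D2:**
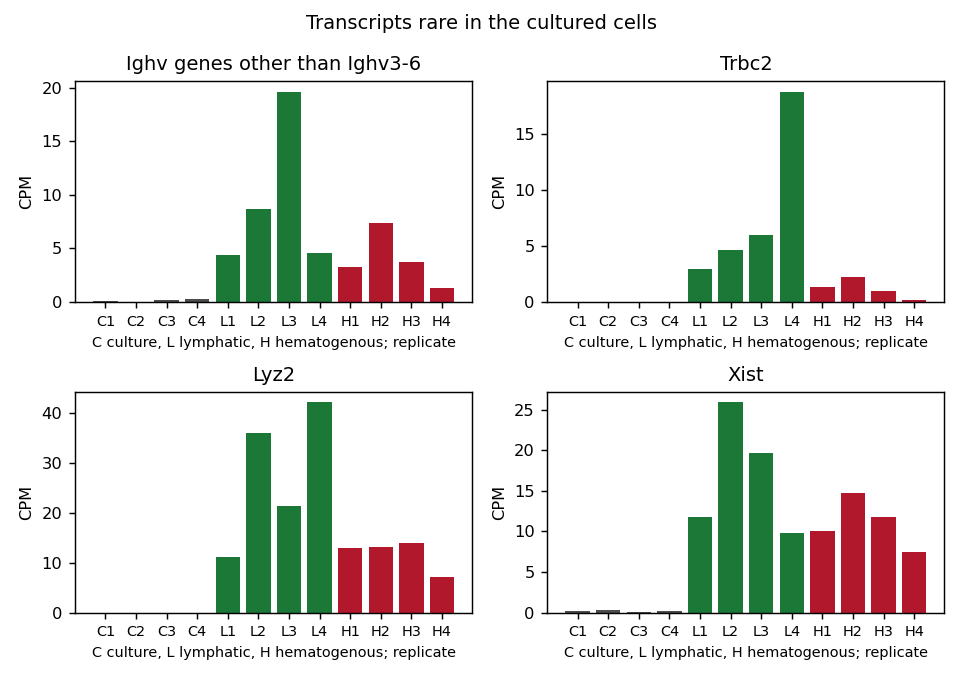
CPM per library of heavy chain V genes other than Ighv3-6, Trbc2, Lyz2 and Xist, 1 bar per library, grey for culture, green for lymphatic and red for hematogenous. The bars of culture lie near 0 in each panel, and lymphatic libraries hold the highest bars.

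Libraries of cells that reached lymph nodes through lymphatic vessels held more transcripts of interferon-stimulated and antigen presentation genes. They held fewer transcripts of sterol and fatty acid synthesis and of hypoxia and glucose-handling genes. They also held fewer transcripts of Tgfb2, Tgfb3, the laminin chain Lama5, Egr2 and Bhlhe40, which cultured cells carried. The immediate early list, which holds Egr2, was not called as a whole (median log2 −0.23). Of the called lists behind these changes only sterol synthesis and hypoxia kept the call with an estimated correlation. Most T cell and macrophage markers rose alongside, some of them from levels already present in culture. Myc itself, which drives this lymphoma, did not move (log2 −0.05 ± 0.131, adjusted p = 0.797, 577 ± 97.5 against 599 ± 54.2 CPM).

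Against culture, 1816 genes were higher and 1753 lower in lymphatic libraries, 26.4% of those tested, with 646 and 758 changed at least 2-fold. Of 35 splits of these 8 libraries, the real one included, the others gave 0 genes at most. In 30.1% of genes the groups did not overlap, against 2.86% expected by chance. Of 42 lists tested, 21 were called, 14 higher and 7 lower. As many lists came from 5 of 35 splits, the real one included, and the highest other split gave 22. The others among these were uneven mixes, which keep part of the group difference, and evenly mixed splits gave at most 9. Only cholesterol biosynthesis and hypoxia response kept the call when the correlation between list genes was estimated from the data.

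The largest rises were in genes that culture barely expressed. Lyz2, the lysozyme of myeloid cells, reached 27.61 ± 14.02 CPM from 0 counts, at least 361-fold (adjusted p = 7.33e-06), and Ly6a, an interferon-inducible surface antigen, rose at least 186-fold (7.13e-05). Rasgrp1, a Ras exchange factor of lymphocytes, rose from 0.0722 to 37.4 ± 7.22 CPM (count ratio 675, 95% counting interval 187 to 5576, adjusted p = 3.86e-09). Interferon-induced antiviral genes followed, with count ratios of 1113 (199 to 43980) for Rtp4, 732 (202 to 6048) for Mx1, 459 (82.2 to 18170) for Oas1a, 437 (78.2 to 17280) for Ifitm1 and 254 (70.2 to 2102) for Oas3. Ifitm3, which blocks virus entry, rose by log2 8.69 ± 0.737 (1.64e-06) and the oligoadenylate synthetase Oas2 by 8.37 ± 0.679 (1.07e-06). The interferon-inducible GTPase Tgtp2 (count ratio 248, 84.5 to 1202) and the lymphocyte GTPase Gimap4 (215, 59.2 to 1775) rose as well.

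Among losses, Tgfb3, a TGF-beta ligand, fell from 19.1 ± 0.769 to 0.104 CPM (log2 −7.44 ± 0.329, adjusted p = 9.08e-09) and Lama5, a laminin chain, from 15.1 ± 2.06 to 0.107 CPM (−6.94 ± 0.330, 1.05e-08). The transcription factors Bhlhe40 (−4.19 ± 0.197, 1.05e-08), induced by hypoxia and activation, and Egr2 (−4.29 ± 0.279, 1.75e-07), induced by antigen receptor signals, fell too. So did the adhesion molecule Alcam (−3.88 ± 0.198), the exchange factor Rasgef1a (−3.97 ± 0.225), the calmodulin regulator Pcp4 (−4.09 ± 0.235) and the anion transporter family gene Slco5a1 (−3.75 ± 0.344). Klrb1c, an NK cell receptor gene, fell from 20.2 ± 1.93 to 0.739 ± 0.315 CPM. Genes known from other tissues were also lost, namely Nyx of the retina (171 ± 18.1 to 6.42 ± 3.87 CPM), Eqtn of sperm (log2 −5.48 ± 0.329) and the orphan receptor Gpr12 (−5.38 ± 0.353).

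Interferon-stimulated genes were the most uniform rise. Of 35 tested genes of the type I interferon response, 34 rose and 0 fell, also when adjusted over the list alone (median log2 4.14, camera adjusted p = 4.85e-20, with estimated correlation adjusted p = 0.190), and only Stat2 was not called. Of 22 interferon gamma response genes, 16 rose, also over the list alone, and 1, Irf8, fell (median 1.71, p = 9.37e-09, estimated correlation p = 0.190). The GTPases Gbp7 (5.77 ± 0.591), Irgm2 (2.90 ± 0.372) and Igtp (2.47 ± 0.313) were among the genes that rose. T cell markers moved with them, 20 of 21 higher, also over the list alone (median 5.22, or 4.67 with genes of 0 counts set to their lower bound, p = 2.55e-13, estimated correlation p = 0.173). Their summed CPM went from 92.1 ± 4.94 to 254 ± 54.7, with Trbc2 at 8.09 CPM from 0, while Lck, Cd2 and Il7r were present in culture already. Of 11 macrophage and monocyte markers, 9 rose and 2, Csf1r and Itgam, fell, also over the list alone (p = 1.23e-03, estimated correlation p = 0.262).

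Antigen presentation rose on both classes. Of 13 MHC class II genes, 10 rose (11 adjusted over the list alone) and 1, H2-Eb2, fell (median 2.71, camera adjusted p = 1.12e-06, estimated correlation p = 0.217). The class II chains H2-Aa (209 ± 78.7 against 15.9 ± 2.25 CPM, log2 3.71 ± 0.233) and H2-Eb1 (4.12 ± 0.292) and the peptide loading genes H2-DMa (3.28 ± 0.438) and H2-DMb2 (3.35 ± 0.393) stood out. Of 20 class I genes, 12 rose (16 over the list alone) and 0 fell (median 0.77, p = 2.62e-06, estimated correlation p = 0.262). Members included H2-T23 (1.97 ± 0.317), H2-K1 (1.77 ± 0.281), H2-D1 (1.73 ± 0.276) and the immunoproteasome subunit Psmb9 (1.32 ± 0.282). Galectins rose in 4 of 7 genes (5 over the list alone, median 1.11, p = 1.25e-03, estimated correlation p = 0.125). These included Lgals9 (1.48 ± 0.130), Lgals3bp (6.39 ± 0.443), Lgals3 and Lgals4. Plasma cell markers rose in 3 of 4 genes, Ighg1, Ighg2b and Derl3, also over the list alone (p = 0.0456, estimated correlation p = 0.342, p = 0.142 without lymphatic 4).

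Lipid synthesis fell in a block. All but Ebp of the 24 cholesterol biosynthesis genes were lower, also over the list alone (median −1.89, camera adjusted p = 1.22e-26, estimated correlation p = 0.0398), and their summed CPM went from 6277 ± 112 to 1553 ± 239. Hmgcs1, an early enzyme of the pathway (582 ± 18.7 to 89.0 ± 16.3 CPM, log2 −2.71 ± 0.128), the sterol sensor partner Insig1 (−2.80 ± 0.148), the kinase Pmvk (−2.65 ± 0.234) and the demethylation enzyme Msmo1 (−2.46 ± 0.120) fell most clearly. Of 13 fatty acid synthesis genes, 11 fell (12 over the list alone) and 0 rose (median −1.17, p = 2.53e-09, estimated correlation p = 0.166). The set included the desaturases Fads2 (−3.68 ± 0.281), Scd2 (−2.16 ± 0.183), Scd1 (−1.78 ± 0.152) and Fads1 (−1.48 ± 0.186). Fatty acid oxidation moved up in 7 of 21 genes (10 over the list alone, median 0.36, p = 2.72e-03, estimated correlation p = 0.294). Among them were the trifunctional subunits Hadhb (0.79 ± 0.111) and Hadha (0.45 ± 0.104).

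Hypoxia response genes fell in 14 of 20 cases and rose in 0, also over the list alone (median −0.83, camera adjusted p = 1.12e-06, estimated correlation p = 0.0398). The stress gene Ddit4 (−1.73 ± 0.276) and the demethylase Kdm3a fell too. Glycolysis fell in 10 of 20 genes and rose in 1, Slc16a1, also over the list alone (median −0.39, p = 1.23e-03, estimated correlation p = 0.302), and fell in 13 and rose in 3 without lymphatic 4. Its largest falls were the lactate exporter Slc16a3 (−1.49 ± 0.341) and the glucose transporter Slc2a1 (−1.30 ± 0.260), then Hk1 and Pfkm. TGF-beta response fell in 5 of 18 genes, also over the list alone (median −0.36, p = 1.78e-03, estimated correlation p = 0.125), namely Tgfb3, the receptor Tgfbr2 (−1.78 ± 0.137), Tgfb2 (−1.42 ± 0.168), Smad7 (−1.31 ± 0.192) and Ldlrad4, and without lymphatic 4 it fell in 8 and rose in 1. Of 24 p53 targets, 8 fell (9 over the list alone) and 1, Rrm2b, rose (median −0.21, p = 0.0205, estimated correlation p = 0.217, p = 0.0514 without lymphatic 4), with Trp53inp1 (−1.78 ± 0.211), Zmat3 (−1.26 ± 0.203) and Sesn1 (−1.20 ± 0.291). Replication-dependent histone genes fell in 5 of 11, also over the list alone (median −0.99, p = 0.0272, estimated correlation p = 0.495, p = 0.072 without lymphatic 2), and in 1 without culture 4. Their summed CPM was 29.5 to 37.0 in lymphatic 1 to 3, 78.8 in lymphatic 4 and 48.9 to 76.2 in culture. These low values cover poly(A) RNA only and may not measure histone expression.

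Growth-related lists shifted by small amounts. Of 40 MYC targets and ribosome biogenesis genes, 20 rose (23 over the list alone) and 0 fell (median 0.36, camera adjusted p = 8.25e-06, estimated correlation p = 0.190), and 11 rose without culture 4. Npm1 (0.70 ± 0.156) and Nop58 (0.65 ± 0.126) were among the higher genes. Of 17 heat shock genes, 8 rose and 1, Dnajb4, fell (9 and 2 over the list alone, median 0.40, p = 4.38e-03, estimated correlation p = 0.264). The chaperone Hsp90aa1 rose by 0.97 ± 0.123. The ATF4 and amino acid response rose in 8 of 26 genes and fell in 1, Ddit4, also over the list alone (median 0.42, p = 1.78e-03, estimated correlation p = 0.217). Among them were the one-carbon enzyme Mthfd2 (0.95 ± 0.115) and the transaminase Gpt2 (0.93 ± 0.204). Nuclear-encoded oxidative phosphorylation rose in 12 of 75 genes (2 over the list alone, median 0.35, p = 9.17e-04, estimated correlation p = 0.769). It rose in 2 without culture 4, and without lymphatic 4 it rose in 12, fell in 9 and went to median −0.02 and camera adjusted p = 0.988. Cytosolic ribosomal proteins had 0 of 77 genes called by edgeR, also over the list alone, 8 at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma-voom (median 0.32, p = 0.0257, estimated correlation p = 0.785), and went to median −0.15 and p = 0.0693 without lymphatic 4, the library with 15.8% ribosomal protein counts.

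Lists of migration and B cell state were not called as a whole, while some of their genes moved. The transcription factor Klf2 (2.97 ± 0.372) and the integrin Itgal (3.55 ± 0.245) rose. The egress receptor S1pr1 (−2.31 ± 0.207) and the chemokine receptor Ccr7 (−1.19 ± 0.160) fell, and homing as a list had 8 genes higher and 4 lower of 18 (9 and 4 over the list alone, camera adjusted p = 0.187). B cell receptor and mature B cell genes split into 15 higher and 8 lower of 35 (15 and 10 over the list alone, camera adjusted p = 0.187). Ms4a1, which encodes CD20, rose by 4.39 ± 0.288 and Cd180, a receptor of B cells, fell (−1.40 ± 0.144). Rag1 (1.89 ± 0.381) and Rag2 (1.62 ± 0.247), which recombine antigen receptor genes, rose, and Cd93 (−1.47 ± 0.226), Bcl6 (−1.87 ± 0.233) and Bach2 (−1.19 ± 0.206) fell. Rag1 was at 41.5 to 51.3 CPM in lymphatic 1 to 3 but at 10.8 in lymphatic 4, within the culture range of 9.38 to 11.2. Mitosis had 2 genes higher and 0 lower of 30 (0 over the list alone, camera adjusted p = 0.477) and DNA replication 5 higher and 1 lower of 41 (2 and 0 over the list alone, camera adjusted p = 0.709). Without lymphatic 4 the counts were 8 and 1 for mitosis and 8 and 5 for DNA replication, and without culture 4 they were 0 and 0, and 2 and 0.

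Cells that reached lymph nodes through the blood also showed a fall in sterol and fatty acid synthesis, and a fall in hypoxia and glycolysis genes that was larger in median. Of these lists sterol synthesis and hypoxia kept the call with an estimated correlation, and no list of the 4 kept one for the difference between routes. CD20, most class II genes and 21 of 35 B cell receptor and mature B cell genes were higher. Interferon-stimulated genes rose less in median than in the lymphatic group. The interferon and class II calls were lost with an estimated correlation. Myc again stayed level (log2 0.09 ± 0.131, adjusted p = 0.667, 638 ± 58.5 against 599 ± 54.2 CPM).

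Against culture, 1880 genes were higher and 1880 lower in hematogenous libraries, 27.8% of those tested, with 833 and 930 changed at least 2-fold. The counts were 3150 and 3194 when only these 2 groups were fitted, and 2995 and 2935 with lymphatic 4 left out of the shared fit. Of 35 splits, the real one included, the others gave 0 genes at most, and the groups did not overlap in 43.6% of genes. Of 42 lists, 17 were called, 8 higher and 9 lower. As many came from 8 of 35 splits, the real one included, and the highest other split gave 21. The others among these were uneven mixes, and evenly mixed splits gave at most 8. Hypoxia response, cholesterol biosynthesis and mature B cell identity kept the call with an estimated correlation.

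Rasgrp1 went from 0.0722 to 108 ± 12.2 CPM (count ratio 2028, 95% counting interval 561 to 16750, adjusted p = 3.05e-10). Col5a3, a collagen chain, rose at least 199-fold from 0 counts (15.7 ± 5.92 CPM, 5.17e-06) and Lyz2 at least 152-fold (11.8 ± 3.20 CPM, 1.83e-05). Nalcn, a sodium leak channel, rose from 1.29 ± 0.432 to 211 ± 18.6 CPM (log2 7.30 ± 0.191, 2.99e-11). Further rises were in Ltbp2, which binds latent TGF-beta (count ratio 139, 47.4 to 678), the cytoskeletal adaptor Pstpip1 (138, 46.9 to 671), the lysolipid receptor family gene Gpr132 (log2 6.37 ± 0.355), the early B lineage antigen Ly6d (6.17 ± 0.693) and the Schlafen gene Slfn2 (5.96 ± 0.581). Lama5 fell to a count ratio of 611 below culture (109 to 24150), and Tgfb3 (−7.43 ± 0.359), Nyx (−6.31 ± 0.557), Klrb1c (−6.29 ± 0.393) and Eqtn (−5.05 ± 0.343) fell as in the lymphatic group. The desaturase Fads2 (−7.04 ± 0.360, 174 ± 6.23 to 1.30 ± 0.429 CPM), the Notch ligand Jag2 (−6.38 ± 0.557), the stress gene Gadd45g (−5.88 ± 0.596), the hydroxylase Asph (−5.28 ± 0.342), the sulfate activating enzyme Papss2 (−5.27 ± 0.258) and the metallothionein Mt1 (−5.02 ± 0.507) also fell.

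Class II presentation was the strongest list rise. Of 13 genes, 12 rose and 0 fell, also over the list alone (median 4.58, camera adjusted p = 3.35e-12, estimated correlation p = 0.108). The set included H2-Aa at 687 ± 51.1 against 15.9 ± 2.25 CPM (log2 5.43 ± 0.25), H2-Eb1 (5.91 ± 0.313), H2-DMb2 (5.92 ± 0.408) and the class II transactivator Ciita (3.51 ± 0.221). B cell receptor signalling and mature B cell genes rose in 21 of 35 and fell in 1, Cd72 (21 and 3 over the list alone, median 0.58, p = 1.63e-08, estimated correlation p = 2.80e-03), and rose in 22 and fell in 3 without lymphatic 4. Ms4a1 went from 0.788 ± 0.190 to 78.8 ± 12.2 CPM (6.58 ± 0.291), the transcription factor Spib from 95.2 ± 6.25 to 292 ± 31.1 (1.62 ± 0.127), and the receptor signalling genes Siglecg (1.54 ± 0.104) and Bank1 (1.5 ± 0.124) rose. V segments other than the dominant heavy chain segment, a sign of other B cells, summed to 3.92 ± 2.50 CPM against 0.131 in culture. Dendritic cell markers fell in 2 of 4 genes, Zbtb46 and Cst3, also over the list alone (median −0.73, p = 0.0370, estimated correlation p = 0.350, p = 0.0514 without hematogenous 2).

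Type I interferon response genes rose in 23 of 35 cases (24 over the list alone) with 0 lower (median 1.73, camera adjusted p = 9.13e-07, estimated correlation p = 0.380). Among them were Samd9l (2.79 ± 0.277), Cmpk2 (2.59 ± 0.363), Ifi27l2a (2.44 ± 0.455) and the RNA sensor Ddx58 (2.36 ± 0.286). Interferon gamma response genes rose in 13 of 22 (15 over the list alone) and fell in 2, Gbp2 and Cd274 (median 1.24, p = 3.65e-04, estimated correlation p = 0.350). Class I genes rose in 9 of 20, also over the list alone (median 0.45, p = 2.44e-04, estimated correlation p = 0.350). Members included H2-D1 (1.87 ± 0.278) and H2-K1 (1.76 ± 0.282). T cell markers rose in 16 of 21 (17 over the list alone, median 3.54, or 2.87 with bounds, p = 1.22e-06, estimated correlation p = 0.303), though most of their summed 287 ± 54.4 CPM lay in Cd2, Il7r and Lck, and Trbc2 reached 1.18 CPM. Galectins rose in 5 of 7, also over the list alone (median 1.72, p = 1.20e-03, estimated correlation p = 0.103). These included Lgals9 (1.72 ± 0.131), Lgals1 (1.00 ± 0.245), Lgals3, Lgals4 and Lgals3bp.

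Cholesterol biosynthesis fell in 23 of 24 genes, also over the list alone (median −2.23, camera adjusted p = 4.33e-28, estimated correlation p = 0.0223), and summed CPM went from 6277 ± 112 to 1425 ± 118. Insig1 (−3.58 ± 0.154), Msmo1 (−3.24 ± 0.125), Hmgcs1 (−3.16 ± 0.131) and the cyclase Lss (−2.95 ± 0.188) led. Fatty acid synthesis fell in 12 of 13, also over the list alone (median −1.36, p = 2.48e-10, estimated correlation p = 0.108). Fatty acid oxidation rose in 8 of 21 and fell in 1, Acsl1, also over the list alone (median 0.30, p = 0.0193, estimated correlation p = 0.374). The set included the carnitine transferase Cpt1a (27.9 ± 2.42 to 159 ± 37.8 CPM, 2.51 ± 0.228) and the carnitine carrier Slc25a20 (1.73 ± 0.245). Oxidative stress defence fell in 11 of 23 and rose in 4, Gclc, Gclm, Slc40a1 and Cat, also over the list alone (median −0.41, p = 9.21e-03, estimated correlation p = 0.303). Among them were glutathione reductase Gsr (−4.03 ± 0.244) and ferritin Fth1 (−1.46 ± 0.163).

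Hypoxia response fell in 17 of 20 genes (18 over the list alone) and rose in 1, Pfkfb3 (median −1.43, camera adjusted p = 7.62e-11, estimated correlation p = 2.80e-03). Members included Bhlhe40 (−4.80 ± 0.212), the mitophagy gene Bnip3 (93.4 ± 7.44 to 9.71 ± 2.67 CPM, −3.25 ± 0.212) and the prolyl hydroxylase P4ha1 (−2.30 ± 0.131). Glycolysis fell in 15 of 20 and rose in Pfkfb3 alone (15 and 2 over the list alone, median −1.23, p = 6.77e-09, estimated correlation p = 0.111). These included Slc16a3 (−6.10 ± 0.462), Aldoa (−2.33 ± 0.239), Slc2a1 (−2.26 ± 0.274) and Pgk1 (−1.54 ± 0.119). Immediate early genes fell in 13 of 29 and rose in 4 (15 and 4 over the list alone, median −0.58, p = 1.22e-04, estimated correlation p = 0.303), Egr2 (−3.28 ± 0.269) lower and Fosb (3.04 ± 0.355), Fosl2 (2.37 ± 0.476), Egr1 and Klf4 higher. Fosl2 in hematogenous 2, at 5.22 CPM, lay within the culture range of 4.34 to 7.08. Heat shock genes fell in 6 of 17 (7 over the list alone) and rose in 1, Hsp90ab1 (median −0.23, p = 0.0284, estimated correlation p = 0.350), opposite to the lymphatic group. Of 24 p53 targets, 10 fell and 2, Rrm2b and Zfp365, rose, also over the list alone (median −0.36, p = 0.0325, estimated correlation p = 0.303, p = 0.0686 without hematogenous 2).

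Growth-related lists were not called. MYC targets had 5 genes higher and 6 lower of 40 (5 and 7 over the list alone, camera adjusted p = 0.879), and oxidative phosphorylation 0 and 3 of 75 (0 and 2 over the list alone, camera adjusted p = 0.402). Ribosomal proteins had 1 and 1 of 77 (0 and 0 over the list alone, camera adjusted p = 0.323). Without lymphatic 4 the counts were 7 higher and 22 lower for oxidative phosphorylation (camera adjusted p = 0.0889) and 6 and 17 for ribosomal proteins (camera adjusted p = 0.0685). Mitosis had 3 and 3 of 30 (1 and 2 over the list alone, camera adjusted p = 0.806) and DNA replication 4 and 4 of 41 (3 and 3 over the list alone, camera adjusted p = 0.996). For MYC targets, mitosis and DNA replication the counts were 13 and 9, 7 and 4, and 9 and 6 without lymphatic 4, and 2 and 5, 1 and 3, and 2 and 3 without culture 4. Homing receptors had 8 higher and 3 lower of 18 (9 and 3 over the list alone, camera adjusted p = 0.0608), and 10 and 3 without lymphatic 4, where the list was called (camera adjusted p = 0.0398). Itgal (4.57 ± 0.248) and Klf2 (3.61 ± 0.378) were higher, and the lower genes were Cd69 (−2.60 ± 0.222), S1pr1 (−1.86 ± 0.206) and Ccr7 (−1.52 ± 0.162). TGF-beta response had 1 higher and 5 lower of 18, also over the list alone (camera adjusted p = 0.0653). Tgfb1 (0.68 ± 0.181) was higher, and Tgfb2 (−3.79 ± 0.199) and Tgfb3 were the most reduced.

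The routes shared part of their change from culture. Of the called genes, 959 were higher and 1006 lower in both lymph node groups, 1965 in all, against 252 and 243 expected if the lists were independent, and 65 moved in opposite directions. The log2 changes correlated at r 0.790 (jackknife SE 0.0385). Both groups were compared with the same culture libraries, which alone creates correlation: 30 simulations with unchanged groups gave r 0.522 ± 0.00969, 0 shared genes in every run and a covariance of 0.0413 against 0.901 observed. Over all tested genes the share with the same sign in both arms was hardly above that of unchanged groups (67.8% against 67.3%). The simulations gave every group the same spread per gene, pooled over all groups. Real culture libraries varied less than lymphatic ones (Spearman 0.991 to 0.994 against 0.933 to 0.990 within the group). The simulated r and share may therefore be too high. With culture libraries divided between the arms, the shared genes were 1137 to 1173 and r 0.709 to 0.728 over 6 assignments. Of 60 splits, only the real one gave as many shared genes (highest other 0), while 3 gave an r as high (highest other 0.885). Random splits mix the groups and share a mixed reference, which can raise r, so they cannot decide whether r is chance. Without lymphatic 4 the shared genes were 3034.

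**Figure D3:**
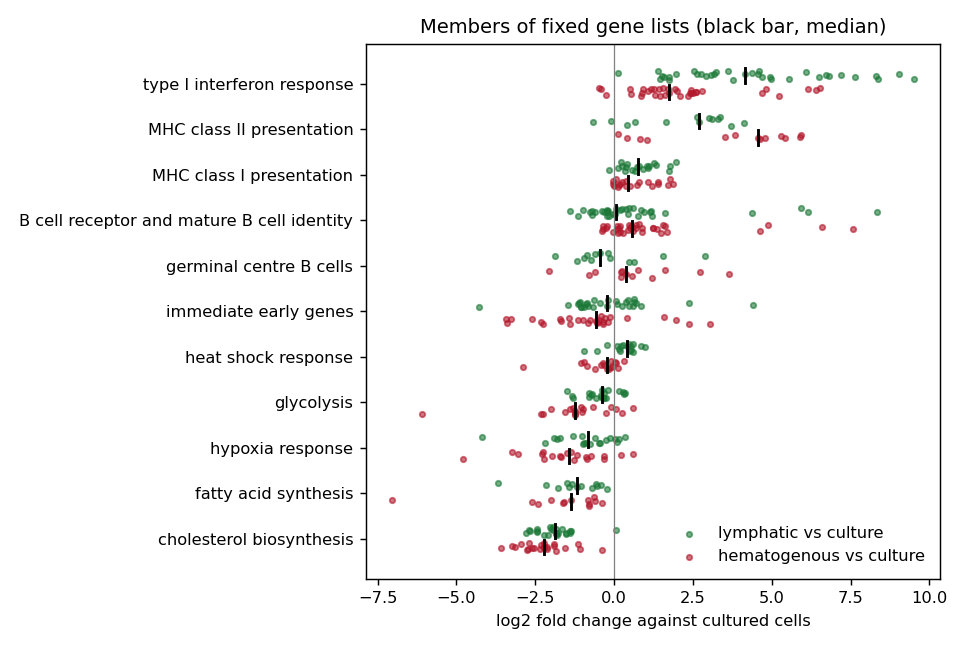
Log2 fold change against culture of each tested gene of 11 lists, 1 point per gene, green for lymphatic and red for hematogenous, with the list median as a black bar. The cholesterol median lies at −1.89 and −2.23, the type I interferon median at 4.14 and 1.73 and the class II median at 2.71 and 4.58.

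Compared directly, lymphatic libraries held more interferon-stimulated transcripts, from lymphoma or other cells, and hematogenous libraries more class II, mature B cell and germinal centre transcripts. The glycolysis, hypoxia, heat shock and immediate early lists were called higher in lymphatic than in hematogenous libraries, and 9 of 24 sterol synthesis genes, low in both, were higher there. Of the lists in this paragraph only mature B cell identity kept its call with an estimated correlation. The list of homing and egress receptors was not called, though some of its genes differed. Myc did not differ (log2 −0.15 ± 0.131, adjusted p = 0.447).

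Between the routes 1542 genes were higher and 1470 lower in lymphatic libraries, 22.3% of those tested, with 543 and 493 changed at least 2-fold. Fitting only these 8 libraries gave 910 and 824, leaving out hematogenous 1 gave 930 higher, and leaving out lymphatic 4 gave 2253 lower. Of 35 splits, the real one included, the others gave 1 gene at most, and the groups did not overlap in 24.6% of genes. Of 42 lists, 18 were called, 15 higher and 3 lower. As many came from 4 of 35 splits, the real one included, and the highest other split gave 19. The others among these were uneven mixes, and evenly mixed splits gave at most 14. B cell receptor signalling and mature B cell identity alone kept the call with an estimated correlation.

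Interferon genes headed the genes higher in lymphatic libraries, with Ifit1 (26.6 ± 19.3 against 0.919 ± 0.524 CPM, log2 4.87 ± 0.646, adjusted p = 2.07e-04), Ifit3 (4.08 ± 0.639), Oasl2 (3.99 ± 0.556), Tgtp2 (3.59 ± 0.513) and the ubiquitin-like Isg15 (3.41 ± 0.504). Others were Slc16a3 (33.3 ± 21.6 against 1.28 ± 0.535 CPM, 4.61 ± 0.450), the exon junction gene Magohb (4.42 ± 0.429), Fndc3c1 of the fibronectin domain family (3.82 ± 0.325), the zinc finger gene Zfp979 (3.81 ± 0.261), Mt1 (3.65 ± 0.486), the neuronal tubulin Tubb3 (3.57 ± 0.420) and Fads2 (3.36 ± 0.348). Hematogenous cells carried more Col5a3 (log2 −6.08 ± 0.515, 0.255 against 15.7 ± 5.92 CPM, adjusted p = 4.43e-05), Ltbp2 (−5.56 ± 0.668), Pcp4 (−4.37 ± 0.236, 1.07e-07) and Nalcn (−2.66 ± 0.139, 1.07e-07). They also carried more of the AP-1 factor Fosl2 (−2.81 ± 0.474), the LIM protein Crip1 (−2.79 ± 0.387), the peroxisomal oxidase Pipox (−2.57 ± 0.308), the sorting receptor Sorl1 (−2.52 ± 0.175), the ubiquitin ligase Neurl1b (−2.39 ± 0.208), the adaptor Lat2 (−2.38 ± 0.278) and the dioxygenase Haao (−2.33 ± 0.298). Fosl2 was at 31.55 to 50.3 CPM in hematogenous 1, 3 and 4, but at 5.22 in hematogenous 2, next to lymphatic 2 at 5.18. Magohb, Ifit3 and Tgtp2 have near-identical copies that can take or lose reads, so their values are uncertain.

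**Figure D4:**
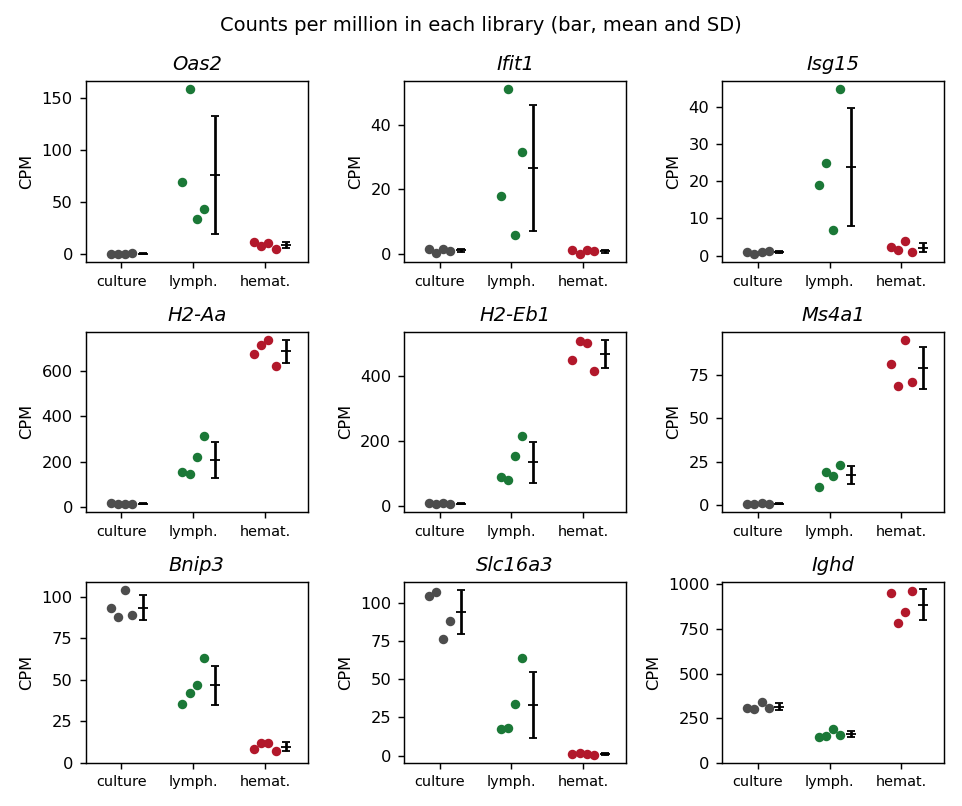
CPM of 9 genes in each library, 1 point per library, with the group mean and SD as a bar. Interferon genes are highest and most scattered in lymphatic libraries, class II genes, Ms4a1 and Ighd highest in hematogenous libraries, and Bnip3 and Slc16a3 highest in culture.

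Type I interferon genes were higher in 30 of 35 cases and lower in 0, also over the list alone (median 1.93, camera adjusted p = 9.66e-13, estimated correlation p = 0.357), and in 32 without lymphatic 4. Their summed CPM was 1352 ± 519 in lymphatic, 586 ± 80.7 in hematogenous and 241 ± 8.23 in culture libraries. T cell markers moved the same way in 15 of 21, with 1, Il7r, lower (17 and 3 over the list alone, median 1.88, p = 1.35e-04, estimated correlation p = 0.462), and 13 were higher and 3 lower without lymphatic 4. So did macrophage and monocyte markers, 5 higher and 1, Mrc1, lower of 11 (9 and 1 over the list alone, median 1.26, p = 0.0154, estimated correlation p = 0.462, p = 0.0510 without lymphatic 2), at 94.9 ± 38.4 against 52.4 ± 4.86 summed CPM. Interferon gamma genes were higher in 13 of 22 and lower in 2, Irf8 and Ciita (14 and 2 over the list alone, median 0.99, p = 6.08e-03, estimated correlation p = 0.504, p = 0.0694 without lymphatic 4), with Gbp2 at 2.32 ± 0.314. Dendritic cell markers were higher in 3 of 4, Zbtb46, Bst2 and Cst3, also over the list alone (p = 0.0287, estimated correlation p = 0.440), and summed to 529 CPM in lymphatic 4 against 199 to 245 in the other lymphatic libraries. Cultured cells held 231 to 282 CPM of these markers, so the sum does not measure dendritic cells alone. Class I genes had 0 of 20 called by edgeR, also over the list alone, 5 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (list camera adjusted p = 0.734), but 1 higher and 7 lower without lymphatic 4 (median −0.10 against 0.09, camera adjusted p = 0.398).

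Class II genes were lower in lymphatic cells in 11 of 13 cases and higher in 0, also over the list alone (median −1.72, camera adjusted p = 6.72e-09, estimated correlation p = 0.217). Members included the invariant chain Cd74 (453 ± 196 against 1734 ± 171 CPM, log2 −1.94 ± 0.249), Ciita (−1.85 ± 0.201), H2-DMa (−2.01 ± 0.352) and H2-DMb2 (−2.58 ± 0.321). Mature B cell genes were lower in 17 of 35 and higher in 4, Fcer2a, Fcgr2b, Blnk and Prkcb (18 and 4 over the list alone, median −0.39, p = 1.93e-06, estimated correlation p = 0.0150). These included Ms4a1 (17.2 ± 5.28 against 78.8 ± 12.2 CPM, −2.20 ± 0.208), the BAFF receptor Tnfrsf13c (−1.25 ± 0.143), Cd180 (−1.18 ± 0.143) and Spib (−1.15 ± 0.125). Germinal centre genes were lower in 7 of 13 (9 over the list alone) and higher in 0 (median −0.66, p = 8.66e-05, estimated correlation p = 0.0892). The set included Irf8 (−1.44 ± 0.168), Bach2 (−1.41 ± 0.207) and Aff3 (−1.34 ± 0.149). Heavy chain V segments other than the dominant one, which would mark other B cells, summed to 9.31 ± 7.16 CPM in lymphatic and 3.92 ± 2.50 CPM in hematogenous libraries, with overlapping ranges (4.40 to 19.6 and 1.33 to 7.32). The survival gene Bcl2 (−0.95 ± 0.102) and the BH3 gene Bmf (−1.98 ± 0.305) were lower and Rag1 (2.25 ± 0.387) higher in lymphatic cells. Rag1 was at 41.5 to 51.3 CPM in lymphatic 1 to 3, 10.8 in lymphatic 4 and 4.75 to 10.6 in hematogenous libraries.

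Glycolysis was higher in 14 of 20 genes (16 over the list alone) and lower in 1, Hk1 (median 0.73, camera adjusted p = 7.06e-06, estimated correlation p = 0.25). Among them were Aldoa (1.63 ± 0.234), Pgk1 (1.12 ± 0.118) and Ldha (1.03 ± 0.173). Hypoxia response was higher in 10 of 20 (13 over the list alone) and lower in 0 (median 0.51, p = 2.73e-04, estimated correlation p = 0.0892). Members included Bnip3 (2.25 ± 0.206) and P4ha1 (1.85 ± 0.129). Cholesterol biosynthesis was higher in 9 of 24 and lower in 1, Cyp51 (11 and 2 over the list alone, median 0.45, p = 1.27e-03, estimated correlation p = 0.462), and higher in 14 without lymphatic 4. The synthase Fdps had the largest difference (0.86 ± 0.142). Oxidative stress defence was higher in 12 of 23 and lower in 1, Cat, also over the list alone (median 0.51, p = 7.15e-04, estimated correlation p = 0.217). The set included Txnrd1 (0.78 ± 0.134) and Prdx6 (0.74 ± 0.107). Fatty acid oxidation divided into 5 higher and 5 lower of 21, also over the list alone (camera adjusted p = 0.945). The carnitine genes Cpt1a (−2.25 ± 0.223) and Slc25a20 (−1.49 ± 0.236) were lower in lymphatic cells.

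Heat shock genes were higher in lymphatic cells in 12 of 17 (13 over the list alone) and lower in 0 (median 0.56, camera adjusted p = 2.86e-07, estimated correlation p = 0.0892). Members included Hsph1 (472 ± 132 against 171 ± 25.2 CPM, log2 1.47 ± 0.172) and Hspe1 (1.20 ± 0.224). Immediate early genes were higher in 14 of 29 and lower in 3, Fosl2, Egr1 and Egr2 (16 and 5 over the list alone, median 0.76, p = 9.54e-04, estimated correlation p = 0.440), and 14 and 6 without lymphatic 4. Rgs2, a brake on G protein signals (2.04 ± 0.11), and Fosb (1.37 ± 0.313) were higher. MYC targets were higher in 14 of 40 (18 over the list alone) and lower in 0 (median 0.39, p = 1.32e-05, estimated correlation p = 0.25), and 16 and 2 without lymphatic 4. The set included Wdr74 (0.99 ± 0.144) and Hspd1 (0.82 ± 0.11). The unfolded protein response was higher in 5 of 19 (6 over the list alone) and lower in 1, Herpud1 (median 0.30, p = 2.69e-03, estimated correlation p = 0.357), and in 8 and 1 without lymphatic 4. The chaperone Hspa5 was higher by 0.69 ± 0.138. Oxidative phosphorylation was higher in 10 of 75 (9 over the list alone, median 0.45, p = 2.52e-06, estimated correlation p = 0.712), and in 13, with 2 lower, without lymphatic 4 (median 0.08, camera adjusted p = 0.0456). Ribosomal proteins were higher in 5 of 77 (0 over the list alone, median 0.40, p = 2.41e-04, estimated correlation p = 0.818), in 3 without culture 4, and had p = 0.999 without lymphatic 4.

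Homing and egress receptors had 2 higher and 2 lower of 18 (3 and 3 over the list alone, camera adjusted p = 0.734), and 3 higher and 6 lower without lymphatic 4 (camera adjusted p = 0.322). With all libraries Cxcr5 and Cd69 were higher and Itgal (−1.02 ± 0.193) and S1pr2 (−0.58 ± 0.128) lower. Adhesion molecules had 2 higher and 4 lower of 22, also over the list alone (camera adjusted p = 0.728). The lower genes were the integrins Itga6 (−0.98 ± 0.205), Itgal and Itgb3 and the junction gene Pecam1 (−0.64 ± 0.120), and Vcam1 and Itga5 were higher. Checkpoint and costimulatory ligands had 1, Cd274, higher (0.85 ± 0.189) and 4 lower of 16 (2 and 5 over the list alone, camera adjusted p = 0.0976). The lower genes were Tgfb1 (−1.17 ± 0.181), Icosl (−1.08 ± 0.248), Btla (−1.02 ± 0.155) and Nectin2. Mitosis had 3 higher and 1 lower of 30 (3 and 0 over the list alone, camera adjusted p = 0.756) and DNA replication 3 higher and 5 lower of 41, also over the list alone (camera adjusted p = 0.728). Without lymphatic 4 these counts were 9 and 4, and 5 and 6.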

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

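All tests of explanations in this part were chosen after the results were seen. Among 237 groups of 4 values tested, 20 had a library far from the other 3, against about 11.8 expected by chance.

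Lymphatic 4 had 15.81% of counts in ribosomal protein genes (others 7.46% to 8.73%), 13.18% of reads not uniquely placed (9.65% to 10.1%) and 529.3 summed CPM of dendritic cell markers (198.8 to 244.6). Culture, without dendritic cells from a lymph node, held 231 to 282 CPM of these markers. Its deviation from the other lymphatic libraries fell with transcript length across genes (rho −0.5772, against at most 0.4748 in size for the other libraries, partly by construction; genes are not independent), as a length bias would give. Genes matched to ribosomal proteins on length rose by 0.8448 (quartiles 0.5595 to 1.194) against 1.214 for the ribosomal proteins, so length and a real rise cannot be told apart for these; an earlier, poorer match had given 0.4267. A lower share of lymphoma cells stays open, since the V segments of the clone moved apart, with Igkv3-7 at 0.9139 of its mean in the others, within their spread, and Ighv3-6 at 0.3228, and since Trbc2 (18.8 against 2.91 to 5.99 CPM) and Lyz2 (42.1 against 11.2 to 35.9) were highest here but Xist lowest (9.84 against 11.8 to 25.9). The design gives no biological difference for this library, and none was tested.

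The type I interferon list was higher in lymphatic than hematogenous libraries by 1.989 ± 0.403 in mean log2 CPM. Lymphatic 4 alone is excluded, since 32 of 35 genes were called without it. Adjusted for T cell markers the difference was 1.948 ± 0.831 (95% interval −0.188 to 4.083), and for macrophage markers 1.197 ± 0.527 (−0.158 to 2.552), so reads from these cells and a change in lymphoma cells cannot be told apart with 8 libraries. Culture itself expressed 4 of 21 T cell markers above 1 CPM (Lat, Lck, Cd2 and Il7r at 1.76, 6.02, 34.1 and 48.4) and 5 of 11 macrophage markers, and of the others Lyz2, Tcf7 and Trbc2 were the most abundant in lymphatic libraries (27.61, 9.52 and 8.09 CPM); the sort gate is not given in the sources used here. Route and day stay open, untested.

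The class II list was higher in hematogenous than lymphatic libraries by 1.494 ± 0.252. Adjusted for other heavy chain V segments the difference was 1.556 ± 0.331 (0.706 to 2.406), and for macrophage markers 1.746 ± 0.413 (0.685 to 2.806), which argues against carried-over B cells or macrophages as its whole cause. Without lymphatic 4, 12 of 13 genes were called. Route and day stay open, untested.

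Other libraries far from their group were lymphatic 2 in genes detected (25350, others 21480 to 22010), culture 4 in predicted genes (2.594% of counts, others 1.584% to 1.744%), hematogenous 3 in dendritic cell markers (153.5 CPM, others 122.1 to 124.0) and hematogenous 4 in Lyz2 (7.028 CPM, others 12.84 to 13.99). Genes near 0 in culture had their counts in 1 library: Rtp4 (0.1152 CPM), Mx1 (0.2305) and Oas1a (0.1152) in culture 4, Ifitm1 (0.1075) and Oas3 (0.215) in culture 3 and Gimap4 (0.1556) in culture 1. The same held for Lama5 in hematogenous 1 (0.08028). Lymphatic 1 stood apart in Tgfb3 (0.2029) and Klrb1c (0.2706), lymphatic 3 in Alcam (1.341), hematogenous 1 in Bhlhe40 (1.686), culture 2 in Eqtn (13.03) and culture 1 in Crip1 (20.77), all in CPM.

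The arms moved in opposite directions from culture, with the difference tested directly, for Magohb (difference 4.424, from 2.31 and −2.11, adjusted p = 2.84e-05), Tubb3 (3.573, from 1.55 and −2.02, 9.75e-05) and the heat shock list (median difference 0.558, from 0.40 and −0.23, 2.86e-07, but estimated correlation p = 0.0892).

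For the counts of genes, 1 of 35 splits, the real one, gave as many as 3569, 3760 and 3012 (highest other 0, 0 and 1). For the 1965 shared genes it was 1 of 60 (highest other 0). Other splits mix the groups, which widens the spread within each side and leaves little to call. The result speaks against chance for the grouping as a whole. It does not say how many of the called genes are chance. For the counts of lists, 5, 8 and 4 of 35 splits, the real one included, gave as many as 21, 17 and 18 (highest other 22, 21 and 19). The other splits among these were uneven mixes, which keep part of the difference between the groups. Splits with equal numbers of each group on both sides gave at most 9, 8 and 14 lists. This test therefore cannot decide whether the counts of lists are chance. For the correlation of the arms, 3 of 60 splits, the real one included, reached 0.7898 (highest other 0.885). Those splits mix the groups and share a mixed reference, so real differences can raise their correlation. The test therefore cannot decide on chance for the correlation either. With culture libraries divided between the arms, which removes the shared reference, r was 0.709 to 0.728.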

How the results depend on the processing

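Alternatives were planned, except the removal of lymphatic 4 and culture 4 together, which was chosen after seeing the data. Each of the 75 changes named by the rule, some of them of the same gene in other comparisons, kept its direction and its side of the threshold under every alternative run for it. With those named from lists there were 415 changes, which kept their direction too. Of these 42 fell short of the threshold in fits of the 2 groups compared, 31 with the replicate number as a block and 16 with limma-voom. So did 12 without a low-count filter, 12 with both libraries out, 3 with upper-quartile factors and 3 without mitochondrial and immunoglobulin genes. With RLE it was 1, with DESeq2 0, and with 1 library left out 4 to 33. Counts of genes stayed within 1.5 times under RLE, upper-quartile, DESeq2, limma-voom, either filter and the block. The lowest and highest counts with 1 library left out were 1317 to 2440 higher and 1341 to 2468 lower for lymphatic with culture, 1545 to 2995 and 1580 to 2935 for hematogenous with culture, and 930 to 2080 and 1072 to 2253 between the routes. The high ends were without lymphatic 4. Fitting only the groups compared gave 3150 and 3194 for hematogenous with culture and 910 and 824 between the routes, and the cause was not tested. The main fit shares 1 spread per gene over groups that varied unequally. Spearman correlations within a group were 0.933 to 0.990 in lymphatic, 0.991 to 0.994 in culture and 0.986 to 0.993 in hematogenous libraries. Its SE and p can therefore be too small in comparisons with lymphatic and too large for hematogenous with culture. Without both libraries the counts were 2063 and 2128, 2609 and 2562, and 1928 and 2094.

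Genes shared by the arms were 1557 to 3034 with 1 library left out, 2566 without both, and 1173, 1161, 1163, 1144, 1169 and 1137 when culture libraries were divided between the arms, which leaves 2 culture libraries per arm. Their correlation was 0.769 to 0.805 with 1 library left out, 0.744 without a low-count filter, which adds genes with few counts, and 0.713, 0.725, 0.728, 0.715, 0.709 and 0.710 with culture divided, which removes the shared reference. Separation R² was 0.625 to 0.734 for the groups and 0.385 to 0.526 for the routes with 1 library left out.

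Lists called fell from 21, 17 and 18 to 2, 3 and 1 with an estimated correlation, which widens the test by construction, and fry, which tests each list without the other genes, called 28 for hematogenous with culture. With 1 library left out they were 17 to 22, 15 to 20 and 17 to 18. Against culture in lymphatic libraries, oxidative phosphorylation changed sign without lymphatic 4 (camera adjusted p = 0.988) and without both libraries (0.807), and was 3.01e-06 at its lowest, without lymphatic 2. Ribosomal proteins changed sign likewise (0.0693 and 0.0204, the latter called in the other direction) and were 9.17e-05 without lymphatic 2. The cause was not tested.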

Other observations

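The arms differed in immunoglobulin expression, in genes chosen after their values were seen. Ighd, the constant region of IgD, was at 315 ± 17.5 CPM in culture, 161 ± 18.4 in lymphatic and 885 ± 86.5 in hematogenous libraries (between the routes log2 −2.46 ± 0.116, edgeR adjusted p = 6.05e-08). Igkc rose from 648 ± 57.7 to 2069 ± 739 and 1306 ± 59.3 CPM, while Iglc2 fell from 134 ± 13.9 to 59.6 ± 21.0 and 23.2 ± 3.58 CPM. Dntt, which adds bases at V segment joints, was at 1.65 ± 0.866, 5.29 ± 3.34 and 0.0475 ± 0.0950 CPM. In all, 65 genes were called in opposite directions by the arms. Pax5, a B cell identity factor, was lower in lymphatic (log2 −0.39) and higher in hematogenous cells (0.50), as were Irf8, Aff3, Tnfrsf13c, Bcl2 and H2-Eb2, and Cacybp, Hsph1, Hspd1, Nolc1 and Rrp12 moved the other way.

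Markers of other cells that had too few tested genes for a list test were low. Their summed CPM in culture, lymphatic and hematogenous libraries were 20.7 ± 2.19, 7.78 ± 5.30 and 2.17 ± 1.20 for NK cells, 0.422 ± 0.417, 1.16 ± 0.170 and 4.30 ± 2.20 for neutrophils, 1.00 ± 0.901, 7.10 ± 5.40 and 1.54 ± 1.24 for stromal cells, and 4.21 ± 0.776, 3.57 ± 0.878 and 6.84 ± 3.15 for platelets. The NK cell receptor gene Klrb1c alone was at 20.2, 0.739 and 0.222 CPM in these groups. The fall of the NK cell sum therefore goes with 1 gene that cultured cells expressed, and does not show fewer NK cells.

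Both tests of hypotheses below were chosen after the results were seen. Hematogenous cells may lie further along the same change from culture as lymphatic cells. Of 610 genes called in all 3 comparisons and moved the same way by both arms, 430, or 70.49%, were further from culture in the hematogenous arm, and 68.39% of 1003 without lymphatic 4, which goes with the hypothesis for most of these genes. Over all 1965 genes called the same way in both arms the share was lower, 60.1% (1181), so it holds for part of the change at most. Xist rose from 0.210 ± 0.105 CPM in culture to 16.8 ± 7.43 and 11.0 ± 3.07 CPM in lymph node libraries, while Y-linked genes had 1 count in total, so its reads could come from female host cells. Over the 8 lymph node libraries Xist went with the mean of T cell and macrophage scores at rho 0.4762 (exact permutation p = 0.2431) and r 0.436 (exact permutation p = 0.2845), and r 0.894 without the 2 libraries farthest from the median, so this cannot be decided with 8 libraries.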
